A study of Mus musculus with 33 samples.

How the data were processed

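The data were single-channel microarray measurements of 33 single mouse blastocysts of the strain (C57BL/6NxDBA/2)F1. Clones had been made by transferring the nucleus of a somatic cell into an enucleated oocyte, and in vitro fertilised (IVF) blastocysts served as controls. Total RNA of each blastocyst was extracted with TRIzol, amplified in a pair of linear rounds to aminoallyl RNA, labelled with Cy3 and hybridised to an Agilent 4x44K array, per the labels' protocols. The arrays fell into 8 groups by the donor and the sex in the labels: blastocysts cloned from male Purkinje cells (n = 4), male hippocampal CA1 cells (n = 4), neonatal Sertoli cells (n = 4), female Purkinje cells (n = 4), female CA1 cells (n = 4) and cumulus cells (n = 3), and male (n = 7) and female (n = 3) IVF blastocysts. All clones were treated with trichostatin A, an inhibitor of histone deacetylases, at 50 nM for 1 h during activation, 5 h with cytochalasin B and 2 h thereafter, and all embryos were cultured for 96 h, per the labels. The labels number the replicates of a group and say that RNA came from single blastocysts. They do not say how many donor animals or transfer sessions lay behind a group, so p-values measure only the spread between these samples, which may be technical.

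The deposited scanner files held the intensity of each spot as the Agilent Feature Extraction software wrote it, on a linear scale. The column used was the processed signal, which the software had already corrected for background, per the file headers. The submitters' processing notes named Agilent Feature Extraction 10.5.1 for the series. The headers of 20 arrays gave 10.5.1.1 and scanner G2505C, and those of 13 arrays gave 9.5.3.1 and scanner G2505B. The 13 were all IVF and cumulus arrays, which the series' design text ascribes to an earlier study of the same laboratory. They are called the earlier set here, and the 20 neuronal and Sertoli arrays the present set. In the earlier set 15.7% to 23.3% of the spots had a processed signal at or below 0, against 0% in the present set. The 9 slides and 7 scan days could be told apart from the headers. Each clone group lay on 1 slide of its own, the male IVF arrays on 3 slides, and 1 slide held the 3 female IVF arrays and male IVF replicate 5.

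The authors' deposited value table gave log2 values of the same arrays. Set against the scanner files, it held log2 of the processed signal floored at 1, minus each array's 75th percentile, and centred per probe on the median of the 19 male or of the 14 female arrays. The median absolute difference from values recomputed in this way was 0.009 in males and 0.002 in females. The median of each of its columns lay between -0.59 and 0.77 on the log2 scale. It served as an alternative only, and because of the centring by sex it gave no comparison of male with female IVF blastocysts.

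For the main values the processed signal was divided by each array's 75th percentile over the probes and floored before log2 was taken. Control spots and spots marked as outliers by the software were left out, and spots of a probe were averaged. The earlier set held signals at or below 0 and the present set did not, so 1 floor was set for all arrays, at 0.0929 of the 75th percentile (-3.43 on the log2 scale). On each array the 1st percentile of the signals of probes well above background was taken, and the highest of these over the 33 arrays became the floor. It was set after the files were opened, and 19.9% of the values lay on it. Probes were renamed through the reference gene table by accession (23076 of 41174), symbol (6583) or synonym (3074), and 8441 kept the file's name. The name changed for 8269 probes, and 99.7% of the probes with a chromosome in both sources had the same chromosome. Probes were kept if well above background on over 50% of the arrays of at least 1 group, which left 27966. A probe also needed a value above the floor on at least 3 arrays and at least a pair of values in every group, rules likewise set after the files were opened. The probe with the highest mean over all arrays stood for a gene, which gave 15791 genes, of which 549 were X-linked and 15092 autosomal. Genomic coordinates were not used here. Probes of near-identical families such as Magea, Xlr and Rhox can take up signal of several members, so these were described as families, except Rhox5, which is given by the probe annotated to it.

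Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3. A model of group means was fitted to all 33 arrays together, with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. The residual degrees of freedom were 25 and the median total 27.8. Every adjusted p in the text comes from limma. Changes are differences of mean log2 values, first group minus second. Where a probe was not well above background on any array of a group, or lay on the floor in all of it, the change is a bound and is written as at least N-fold. A floor at each array's own lowest signal well above background would give larger bounds. The 690 missing values, from spots marked as outliers, stayed missing in limma and were replaced by the mean of their group in the gene list tests.

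The comparisons were each of the 6 clone groups with IVF blastocysts of the same sex, 6 comparisons between donors of the same sex, male with female IVF blastocysts, and 2 interactions that asked whether the difference between neuronal clones and IVF blastocysts differed between the sexes. The 25 gene lists, the rule for named genes and all alternatives except those marked below were fixed before the data were examined. The lists covered all X-linked genes except Xist and Tsix, the X inactivation locus, the Magea and Xlr families, the Rhox family, Y-linked genes, paternally, maternally and H3K27me3-dependent imprinted genes, inner cell mass, primitive endoderm and trophectoderm, 2-cell stage and oocyte genes, pan-neuronal, Purkinje, CA1 pyramidal, Sertoli and cumulus cell markers, the p53 response, heat shock and unfolded protein stress, DNA methylation and histone modifiers, glycolysis, cholesterol synthesis, cytosolic ribosomal proteins and the mitochondrial respiratory chain. They were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. The number of members called was counted over all genes and adjusted over the list alone.

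The rule for named genes took Xist and Tsix, up to 4 called members of each list with the largest changes, and the 8 largest rises and 8 largest falls per clone comparison. These had no overlap between the arrays of both groups, were well above background on every array of at least 1 of them, had a gene symbol rather than a clone or accession name, and were not of the Magea, Xlr, Rhox or Zscan4 families. In the interactions overlap was not asked for. For the other comparisons it took 5 and 5, and for genes called the same way in all 6 clone comparisons the 10 with the largest smallest change. Some single genes that the rule took are not reported here.

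The limma and camera steps were tested on simulated data, normal values drawn around the overall mean of each of 15791 genes with its residual spread. For male Purkinje clones against male IVF blastocysts, 41 of 100 genes changed 2-fold and 81 of 100 changed 4-fold were called, with 7 false calls. For cumulus clones against female IVF blastocysts the numbers were 34, 77 and 4. The 75th percentile of the processed signal, the closest measure of depth here, lay between 904.3 and 1465.6 on all arrays outside the Purkinje groups, at 229.7 to 659.1 in the male and at 353.8 to 838 in the female Purkinje clones. The number of arrays limits the precision of each mean.

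The alternatives were quantile normalization of the signal before log2, scaling to the median of each array, normexp background correction with an offset of 50, the authors' value table, no filter and a strict filter on dim probes, the mean of all probes of a gene, a fit of the compared groups alone, a trended and robust prior, array weights, the replicate number, slide or scan day as a block, a minimum of 2-fold, the other gene list tests, and leaving out each array in turn. The plan named the mean signal for normexp. The 20 files of the present set have no mean signal column, so the median signal and median background of all 33 files were used instead, a departure from the plan. Another departure is that quantile normalization was planned on log2 values and done on the signal before log2. A floor at 0.02 of the 75th percentile and a fit without the 5 Purkinje arrays whose 75th percentile lay below 500 were added after the data had been seen. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.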

Results

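Gene expression was measured on 33 arrays, each hybridised with amplified RNA of 1 mouse blastocyst. Blastocysts cloned from adult Purkinje neurons, adult hippocampal CA1 neurons or neonatal Sertoli cells, the supporting cells of the testis, were compared with in vitro fertilised (IVF) blastocysts of the same sex, and so were clones of cumulus cells, which surround the oocyte. There were 4 male Purkinje, 4 male CA1, 4 Sertoli, 4 female Purkinje, 4 female CA1 and 3 cumulus clones, and 7 male and 3 female IVF blastocysts. Values are log2 signals relative to the 75th percentile of each array, for 15791 genes. Between 45.2% and 62.5% of the probes of an array were well above background. The 75th percentile of the signal was 229.7 to 659.1 in male Purkinje clones and 353.8 to 838 in female Purkinje clones, against 904.3 to 1465.6 in the other groups. Replicates of a group correlated across genes at r = 0.92 to 0.982 over 57 pairs, and no pair looked like the same sample entered again. The IVF and cumulus arrays came from an earlier study, with another scanner and software version. Against IVF, donor cannot be told from array set (cumulus clones: from slide and scan day).

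Male and female IVF blastocysts were compared first, as a check of the labels through genes of the sex chromosomes. Ddx3y and Eif2s3y, Y-linked genes of RNA helicase and translation factor families, were at least 109.3-fold and at least 107-fold higher in males (adjusted p = 3.402e-12 and 5.663e-13). Xist, the noncoding RNA that silences an X chromosome, was at least 61.87-fold lower in males (adjusted p = 5.164e-09), with a mean of 2.52 ± 0.62 (SD, n = 3) in females and all 7 males on the floor. Groups on or near the floor add little spread, so the adjusted p of these genes can be too low. Of 12 Y-linked genes 5 were higher, also when adjusted over the list alone, and the list rose by a median log2 of 0.45 (adjusted p = 6.392e-10, and adjusted p = 0.0002998 with an estimated correlation).

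In all, 69 genes differed between male and female IVF blastocysts, 18 higher and 51 lower in males, and 249, 39, 40 and 28 without male replicate 5, male replicate 6, male replicate 7 or female replicate 1. With slide as a random block 9 were higher and 31 lower. The majority turned after normexp background correction, to 7 higher and 6 lower. It also turned with slide as a fixed block and within the slide of both sexes, fits that rest on 1 male array. Rhox5, an X-linked homeobox gene of the placenta and germ line, fell by 3.77 (adjusted p = 0.002577), to 1.00 ± 1.29 (n = 7) from 4.77 ± 0.08 (n = 3). Dpf1, a chromatin remodelling subunit of neurons, fell by 4.08. Of 22 genes of the p53 response 2 were lower, and 10 when adjusted over the list alone, with a list median of -0.69 (adjusted p = 9.776e-09, and adjusted p = 0.05211 with an estimated correlation). X-linked genes had a median of -0.14 (adjusted p = 0.00127, and adjusted p = 0.4044 with an estimated correlation), with 1 higher and 14 lower (3 and 31 adjusted over the list alone). Cholesterol synthesis (median 0.47, adjusted p = 0.000995), cytosolic ribosomal proteins (0.23, 0.0001462), the Rhox family (-0.98, 0.01343) and the X inactivation locus (-0.36, 0.009454) also passed, and with an estimated correlation their adjusted p were 0.4044, 0.5723, 0.1528 and 0.05211. Without female replicate 1 the cholesterol list did not pass (median 0.17, adjusted p = 0.246), nor did the Rhox family (-1.23, adjusted p = 0.0677), nor without female replicate 2 (-0.59, adjusted p = 0.106). The male array of the slide with both sexes kept the directions of Ddx3y, Eif2s3y and Xist, and differed by -6.00 for Rhox5 and -0.55 for Dpf1. Its list medians were 1.07 for Y-linked genes, -0.79 for the p53 response, 0.66 for cholesterol synthesis, -0.08 for X-linked genes and -0.18 for ribosomal proteins, a turn of direction.

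**Figure D1:**
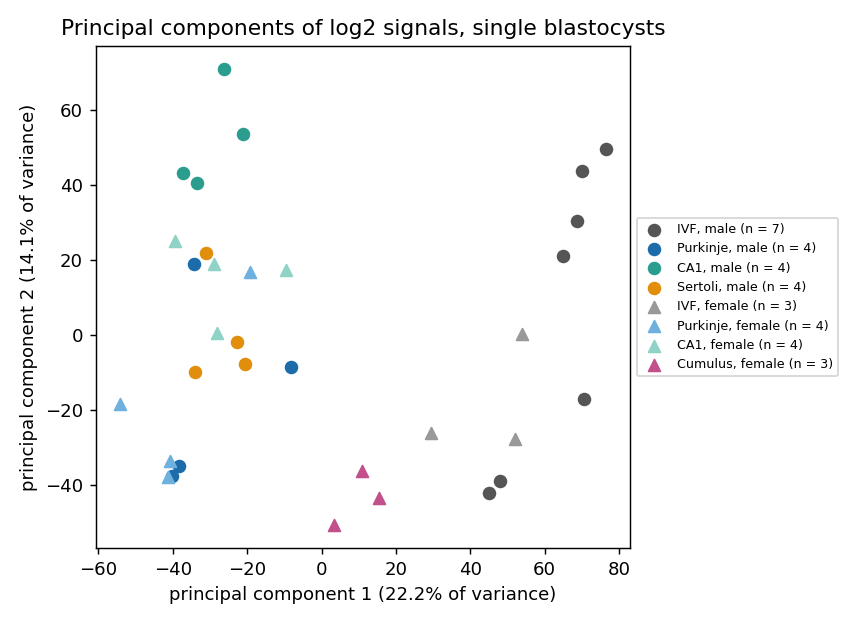
Principal components of the log2 signals of 15302 genes without missing values, 1 point per blastocyst, in arbitrary units; circles are males and triangles females. Component 1 (22.2% of the variance) holds the male IVF blastocysts at 45 to 76.5 and the female at 29.5 to 53.9, the cumulus clones at 3.4 to 15.5, and all other clones at -8.2 or below; component 2 holds 14.1%.

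Clones were compared with IVF blastocysts. Only clones had trichostatin A, so cloning and treatment cannot be told apart in any comparison. Along the principal component with the most variance the groups followed the order of IVF, cumulus and other clones, with means of 63.4 ± 12 (SD, n = 7) and 45.2 ± 13.6 (n = 3) in male and female IVF blastocysts, 9.97 ± 6.12 (n = 3) in cumulus clones and -38.8 to -26.5 in the other 5 groups. This component also parts the earlier from the present array set without overlap. Whether more genes were higher or lower depended on the scaling: in male and female Purkinje clones 63.9% and 66.1% of the genes that passed were higher, against 29.3% and 14.2% with scaling to the array median and 80.6% and 85.9% after normexp background correction.

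Xist and genes of the X chromosome moved apart in the clones. In males, which silence no X chromosome, Xist was at least 47.55-fold higher in Purkinje clones (adjusted p = 1.686e-09), at least 28.52-fold in CA1 clones (adjusted p = 5.147e-09) and at least 86.25-fold in Sertoli clones (adjusted p = 6.301e-11). Its means were 2.14 ± 1.37, 1.4 ± 0.78 and 3.00 ± 0.76 (n = 4 each), and all 12 male clones lay above all 7 male IVF blastocysts. In females Xist rose by 2.54 in CA1 clones (adjusted p = 0.002507) and by 2.56 in cumulus clones (adjusted p = 0.01146), to 5.06 ± 0.41 (n = 4) and 5.08 ± 0.86 (n = 3). The cumulus difference did not pass without IVF replicate 2 (2.31) or cumulus replicate 2 (2.23). In female Purkinje clones the difference of 1.41 did not pass (adjusted p = 0.06556). The brightest of 4 Xist probes stood for the gene. The other 3 changed by 0 to 1.52 in the male clones, and in females they were -0.96, -1.74 and -0.35 in Purkinje clones, -0.36, -0.27 and -0.25 in cumulus clones, and 0.88, -1.24 and 0.20 in CA1 clones, so the rise in cumulus clones rests on 1 probe. Tsix, the antisense gene of Xist, passed in none of the 6 comparisons.

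X-linked genes other than Xist and Tsix fell against autosomal genes in all 6 comparisons. The difference of the medians was -0.26 in male Purkinje clones, -0.53 in male CA1 clones, -0.44 in Sertoli clones, -0.29 in female Purkinje clones, -0.47 in female CA1 clones and -0.32 in cumulus clones. The adjusted p were 5.916e-05, 4.946e-10, 1.027e-10, 4.294e-05, 7.51e-11 and 3.68e-05, and with an estimated correlation adjusted p = 0.2498, 0.06397, 0.07544, 0.286, 0.07195 and 0.3618. Of 549 X-linked genes 123, 185, 163, 100, 93 and 61 were lower and 45, 27, 22, 48, 13 and 3 higher; adjusted over the list alone the lower ones were 124, 193, 178, 111, 109 and 82. In every clone of the 6 groups the mean of these genes lay below that of all IVF blastocysts of the same sex. The earlier study reported this repression partly on the same IVF and cumulus arrays, so the counts are not independent evidence. After normexp background correction the list's own median was positive in male (0.43) and female (0.31) Purkinje clones, where the median of all genes moved by 0.58 and 0.60, and the difference from autosomal genes was -0.14 in the male ones (adjusted p = 0.0672). Without cumulus replicate 2 the difference was -0.18 (adjusted p = 0.055).

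The Magea and Xlr families, X-linked genes of the germ line, fell most of all lists. Of 11 measured genes 9 were lower in each of the 6 comparisons, also when adjusted over the list alone, and 1 was higher in female Purkinje clones. Their medians were -3.97, -4.34 and -4.61 in male Purkinje, CA1 and Sertoli clones and -5.41, -5.18 and -4.87 in female Purkinje, CA1 and cumulus clones. The weakest adjusted p was 1.652e-12, and with an estimated correlation 0.01556. The mean of the families was 0.98 ± 0.48 (n = 7) in male and 1.34 ± 0.42 (n = 3) in female IVF blastocysts, against -2.99 to -2.54 in the clone groups. The earlier study chose these families on the IVF and cumulus arrays, so their direction is not independent evidence. Members share sequence, so the values describe the families.

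**Figure D2:**
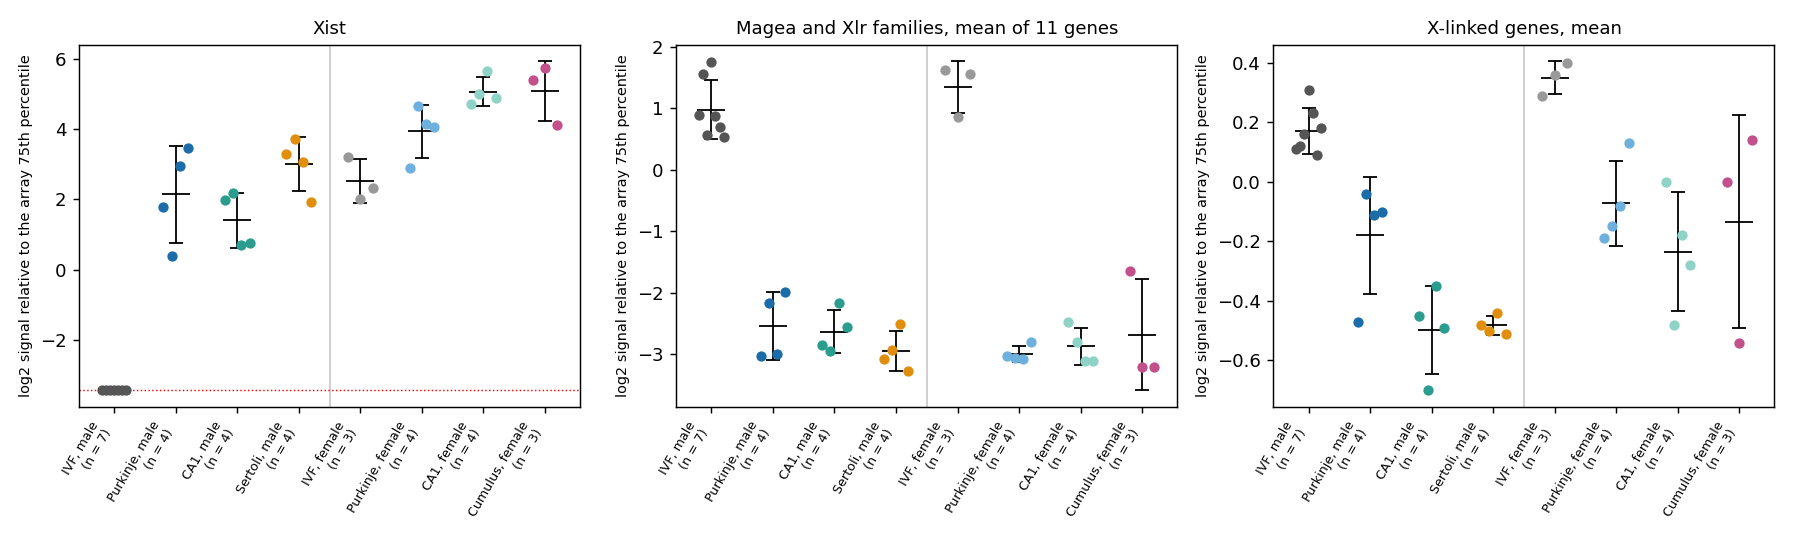
Log2 signal relative to the 75th percentile of the array (vertical axis) of Xist, the mean of 11 Magea and Xlr genes and the mean of X-linked genes, 1 point per blastocyst by group; bars are mean and SD, and the dotted line is the floor of -3.43. All male IVF blastocysts lie on the floor for Xist and all clones lie below all IVF blastocysts for the families; after normexp background correction the list median of X-linked genes was positive in Purkinje clones and below that of all genes.

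In male Purkinje clones 4515 genes differed from male IVF blastocysts, 2886 higher and 1629 lower. Rhox5 rose most among genes well above background, by 6.17 (adjusted p = 3.201e-08), to 7.17 ± 1.12 (n = 4) from 1.00 ± 1.29 (n = 7). Genes of the p53 response rose together: 15 of 22 were higher and 15 higher and 1 lower when adjusted over the list alone, with a median of 1.25 (adjusted p = 7.409e-07, and adjusted p = 0.08962 with an estimated correlation; adjusted p = 0.0562 after normexp background correction). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 3.38 to 1.79 ± 0.52, Plk2, a polo-like kinase, by 4.46, Ccng1, a cyclin, by 2.59, and Pmaip1, a promoter of apoptosis, by 2.74. All 4 clones lay above all 7 IVF blastocysts in the mean of this list.

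Primitive endoderm genes, of the layer that forms the yolk sac, fell in male Purkinje clones by a median of -0.85 (adjusted p = 0.0137, and adjusted p = 0.4988 with an estimated correlation). Of 19, 2 were higher and 8 lower, and 3 and 10 when adjusted over the list alone. Lama1, a laminin chain of the basement membrane, fell by 3.03 (-0.16 at another probe), Amn, a partner in endocytosis, by 3.39, and Sox7, an endoderm transcription factor, by 2.84. The list did not pass without IVF replicate 4 (median -0.68, adjusted p = 0.0513) or with fry (adjusted p = 0.0702). Hand1, a trophoblast transcription factor, was at least 14.87-fold higher and Krt7, a keratin of the trophectoderm, fell by 2.15. Zfp42, a pluripotency marker also known as Rex1, rose by 1.68 (adjusted p = 4.319e-07).

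Genes whose imprint depends on H3K27me3, a repressive histone mark, rose in male Purkinje clones, 6 of 14 with none lower, and 6 and 1 when adjusted over the list alone. The median was 0.85 (adjusted p = 0.01371, and adjusted p = 0.06402 with an estimated correlation), and the list did not pass after normexp background correction (adjusted p = 0.65) or in the authors' values (adjusted p = 0.0929). The amino acid transporters Slc38a4 and Slc38a1 rose by 1.57 and 1.83 and Bbx by 2.05; other probes gave -0.07 to 0.96 for Slc38a1 and -0.27 and 0.43 for Bbx. DNA methylation and histone modifiers fell, 10 of 28 lower and 4 higher (12 and 5 adjusted over the list alone; median -0.44, adjusted p = 0.01321, and adjusted p = 0.06402 with an estimated correlation). Dnmt3b, a de novo DNA methyltransferase, fell by 1.82 to 3.75 ± 0.30 from 5.56 ± 0.25, and Dnmt1, the maintenance enzyme, by 1.73.

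Metabolic genes also moved in male Purkinje clones. Cholesterol synthesis fell by a median of -0.72 (9 of 22 lower and 1 higher, 10 and 2 adjusted over the list alone; adjusted p = 0.0004776, and adjusted p = 0.3139 with an estimated correlation), with Mvd and Mvk of the mevalonate pathway at -2.26 and -2.25 (-0.75 at another Mvk probe). Glycolysis fell by a median of -0.59 (6 of 16 lower and 1 higher, 8 and 2 adjusted over the list alone; adjusted p = 0.02432, and adjusted p = 0.2233 with an estimated correlation). Pgk1, an X-linked glycolytic enzyme, fell by 2.93, and Hk1, a hexokinase, rose by 2.36. Genes of the 2-cell stage rose, 4 of 9 (5 adjusted over the list alone; median 0.91, adjusted p = 0.0137, and adjusted p = 0.3139 with an estimated correlation), and not without Purkinje replicate 4 (median 0.55, adjusted p = 0.157). Ribosomal proteins (33 of 81 higher and 4 lower, 34 and 6 adjusted over the list alone) had a median of 0.35 (adjusted p = 0.00772), which turned to -0.10 after quantile normalization and -0.18 after normexp. Respiratory chain genes (23 of 80 higher and 3 lower, 24 and 3 adjusted over the list alone) had a median of 0.36 (adjusted p = 0.02445), which turned to -0.05 and -0.17. With an estimated correlation both had adjusted p = 0.6939. Ribosomal proteins did not pass without IVF replicate 5 (0.31, adjusted p = 0.0645), nor respiratory chain genes without Purkinje replicate 3 (0.30, adjusted p = 0.0996) or IVF replicates 3, 4 or 5 (adjusted p = 0.0505, 0.06 and 0.109).

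Among other genes of male Purkinje clones, the drug-metabolising acetyltransferase Nat2 rose by 4.59 and the natural killer cell receptor gene Klra7 was at least 23.49-fold higher. The X-linked genes Maoa, a monoamine oxidase, and Plac1, needed in the placenta, fell by 4.51 and 3.80. Car2, a carbonic anhydrase, was at least 14.19-fold lower. The signal of these clones was low: without the 5 Purkinje arrays whose 75th percentile was under 500, a fit added after the data had been seen, which keeps 2 male and 1 female Purkinje array, 1682 genes passed, 1121 higher and 561 lower. In that fit the p53 list kept a median of 1.17 (adjusted p = 2.49e-08), and the 2-cell stage (0.55, adjusted p = 0.119), glycolysis (-0.44, adjusted p = 0.0535), ribosomal (0.18, adjusted p = 0.119) and respiratory chain (0.18, adjusted p = 0.321) lists did not pass.

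In male CA1 clones 4894 genes differed from male IVF blastocysts, 2792 higher and 2102 lower. Rhox5 rose by 6.10 (adjusted p = 7.237e-09), to 7.10 ± 0.64 (n = 4). Cidea, a protein of lipid droplets, rose by 4.66, Anxa8, an annexin, by 4.50, Hic1, a transcriptional repressor, by 4.17 and Slc22a18, an imprinted transporter, by 3.85. Hk1 rose by 3.40 and Hand1 was at least 15.07-fold higher. X-linked genes were among the strongest falls: Plac1 fell by 5.62 (adjusted p = 6.515e-05), Maoa fell by 4.41, Slc7a3, a transporter of basic amino acids, by 4.15, and Pgk1 by 4.13, to 1.43 ± 0.17 from 5.57 ± 0.40.

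DNA methylation and histone modifiers fell in male CA1 clones, 11 of 28 lower and 2 higher (16 and 2 adjusted over the list alone), with a median of -0.70 (adjusted p = 0.001776, and adjusted p = 0.01556 with an estimated correlation). Dnmt3b fell by 2.02 (adjusted p = 1.803e-08), Setdb1, a histone H3K9 methyltransferase, by 1.71, Dnmt1 by 1.39 and Tet3, which oxidises methylcytosine, by 2.12, with 0 at another Tet3 probe. Primitive endoderm genes fell, 9 of 19 lower and 1 higher (10 and 1 adjusted over the list alone), with a median of -1.51 (adjusted p = 0.007544, and adjusted p = 0.6243 with an estimated correlation). Sox7 was at least 10.69-fold lower, Amn fell by 3.45, Lama1 by 3.16 (-0.16 at another probe) and Srgn, a proteoglycan, by 3.63. The p53 list did not pass (median 0.42, adjusted p = 0.107), with 9 of 22 members higher (10 higher and 1 lower adjusted over the list alone). Cdkn1a rose by 2.88, Phlda3, a repressor of Akt, by 2.20 and Bbc3, a promoter of apoptosis, by 1.95. Nefl, a neurofilament, and Rtn1, a reticulon, both neuronal markers, fell by 3.42 and 2.67.

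In Sertoli clones 4077 genes differed from male IVF blastocysts, 2373 higher and 1704 lower. Rhox5 rose by 6.02 (adjusted p = 2.394e-08), to 7.02 ± 0.35 (n = 4), Cidea by 4.64, Itga11, an integrin, by 3.73, Hic1 by 3.71, Nbl1, an antagonist of BMP signals, by 3.64, and Dnajb4, a chaperone, by 3.49 (1.01 at another probe). Hk1 rose by 2.86 and Hand1 was at least 8.516-fold higher. Plac1 fell by 6.37 (adjusted p = 2.676e-05), Dock11, an X-linked exchange factor, by 4.45 (-2 at another probe), Ckap4, a protein of the endoplasmic reticulum, by 4.17, Maoa by 4.07 and Nefl by 3.98.

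Primitive endoderm genes fell in Sertoli clones, 7 of 19 lower and 1 higher (7 and 1 adjusted over the list alone; median -1.01, adjusted p = 0.005591, and adjusted p = 0.4308 with an estimated correlation). Cubn, an endocytic receptor, fell by 3.34, Aqp8, a water channel, by 3.16, Amn by 3.12 and Lama1 by 3.08, with 0.15 at another Lama1 probe. Trophectoderm genes fell, 6 of 23 lower and 2 higher (8 and 2 adjusted over the list alone; median -0.55, adjusted p = 0.01799, and adjusted p = 0.2105 with an estimated correlation), Krt7 by 2.58 and Cldn4, a tight junction protein, by 2.06. The p53 response rose, 7 of 22 (7 adjusted over the list alone; median 0.61, adjusted p = 0.01799, and adjusted p = 0.4308 with an estimated correlation), with Pmaip1 up by 2.59, Btg2 by 2.04 and Sesn1 by 1.63; other probes gave -0.07 and 0.15 for Btg2 and -0.14 and 1.2 for Sesn1. Without Sertoli replicate 4 neither list passed, with a median of -0.33 for trophectoderm and 0.44 for p53 (adjusted p = 0.0944 for both). With the mean of all probes of a gene they did not pass either (adjusted p = 0.0763 and 0.0961), nor did p53 in the authors' values (adjusted p = 0.0597).

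Heat shock and unfolded protein genes fell in Sertoli clones, 6 of 19 lower and 2 higher (7 and 2 adjusted over the list alone; median -0.42, adjusted p = 0.02385, and adjusted p = 0.289 with an estimated correlation), and not without Sertoli replicate 2 (adjusted p = 0.0548) or with the mean of all probes (adjusted p = 0.0833). Ribosomal proteins fell, 19 of 81 lower and 1 higher, also adjusted over the list alone (median -0.28, adjusted p = 0.0004532, and adjusted p = 0.7714 with an estimated correlation). Imprinted genes that depend on H3K27me3 did not pass as a list (median 0.83, adjusted p = 0.1078), with 6 of 14 higher and 1 lower (8 and 1 adjusted over the list alone), among them Gab1, an adaptor of growth factor signals, up by 2.11, and Slc38a4, up by 1.35. Modifiers of DNA and histones did not pass (median -0.47, adjusted p = 0.1562; 4 higher and 4 lower of 28), and Dnmt3b fell by 1.26.

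In female Purkinje clones 3113 genes differed from female IVF blastocysts, 2059 higher and 1054 lower. Dpf1 was at least 41.36-fold lower (adjusted p = 6.855e-06) and Ly75, an endocytic receptor, at least 33.57-fold lower. Lama1 fell by 5.08, with 0 at another probe, Tspan7, an X-linked tetraspanin, by 4.74, Plac1 by 4.56, Nefl by 4.17 and Meg3, an imprinted noncoding RNA, by 4.09. Nat2 rose by 4.72, Klra7 by 4.54, Nexn, an actin-binding protein, by 4.15, Glrb, a glycine receptor subunit, by 3.96 and Hand1 by 3.79. Rhox5 rose by 2.56 (adjusted p = 0.01088), to 7.33 ± 0.85 (n = 4) from 4.77 ± 0.08 (n = 3).

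Primitive endoderm genes fell in female Purkinje clones, 8 of 19 lower and 1 higher (11 and 1 adjusted over the list alone; median -1.56, adjusted p = 4.294e-05, and adjusted p = 0.286 with an estimated correlation), Sox7 by 4.38, Aqp8 by 3.75 and Cubn by 3.37. All 4 clones lay below all 3 IVF blastocysts in the mean of this list. Modifiers of DNA and histones fell, 9 of 28 lower and 4 higher (10 and 4 adjusted over the list alone; median -0.48, adjusted p = 0.0008671, and adjusted p = 0.01534 with an estimated correlation): Dnmt3b by 2.12 (adjusted p = 1.627e-06), Dnmt1 by 2.31 and Tet3 by 2.60, with 0.06 at another Tet3 probe. Zfp42 rose by 1.78, Slc38a1 by 1.65 (0.02 to 0.47 at other probes), Slc38a4 by 1.51 and Ccng1 by 1.89, while the p53 (median 0.33, adjusted p = 0.6058) and H3K27me3 (0.67, adjusted p = 0.1109) lists did not pass, with 2 of 22 and 2 of 14 members higher.

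Ribosomal proteins were higher in female Purkinje clones in 33 of 81 and lower in none (42 adjusted over the list alone; median 0.55, adjusted p = 2.718e-08, and adjusted p = 0.5688 with an estimated correlation), and did not pass after quantile normalization (-0.04, adjusted p = 0.932) or scaling to the array median (adjusted p = 0.0756), and after normexp the test turned, with a median of 0.096 where that of all genes moved by 0.599. Respiratory chain genes were higher in 17 of 80 (19 adjusted over the list alone; median 0.46, adjusted p = 0.0001806, and adjusted p = 0.6302 with an estimated correlation), and did not pass in these either (adjusted p = 0.987, where the median turned to -0.02, and 0.567), and turned likewise after normexp (0.027). Pan-neuronal genes were lower in 2 of 12, also adjusted over the list alone (median -0.63, adjusted p = 0.0133, and adjusted p = 0.04393 with an estimated correlation), and did not pass after normexp (adjusted p = 0.68), quantile normalization (adjusted p = 0.0877) or scaling to the array median (adjusted p = 0.0966), nor without IVF replicate 3 (-0.23, adjusted p = 0.0582). Without the 3 female Purkinje arrays of low signal 309 genes passed, with 1 Purkinje array left and the spread taken from other groups.

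In female CA1 clones 2096 genes differed from female IVF blastocysts, 1326 higher and 770 lower; without CA1 replicate 1 the total was also 1326. Hand1 rose by 4.83 (adjusted p = 0.00024), to 1.55 ± 0.97 (n = 4) from -3.28 ± 0.26 (n = 3), Cd68, a lysosomal protein, by 3.91, Nexn by 3.74 and Mlxipl, a transcription factor that responds to carbohydrate, by 3.41. Dpf1 was at least 41.36-fold lower, Sox7 at least 24.69-fold and Gpc4, an X-linked glypican, at least 21.68-fold. Bend5 fell by 4.71, Nefl by 4.18, Rtn1 by 3.44 and Krt7 by 2.04. Slc38a4 rose by 1.84 and Ebp, an X-linked enzyme of cholesterol synthesis, by 1.48.

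Primitive endoderm genes fell in female CA1 clones, 7 of 19 with none higher (8 lower and 1 higher adjusted over the list alone; median -1.33, adjusted p = 5.949e-05, and adjusted p = 0.2469 with an estimated correlation), Lama1 by 4.14 with 0 at another probe. Heat shock and unfolded protein genes fell, 4 of 19 (4 adjusted over the list alone; median -0.52, adjusted p = 0.01353, and adjusted p = 0.2391 with an estimated correlation); the list did not pass without IVF replicate 3 (-0.34, adjusted p = 0.0527). Setdb1 fell by 1.25 while the modifier list did not pass (median -0.16, adjusted p = 0.1064; 4 of 28 lower and 1 higher). Neither the p53 list (0.30, adjusted p = 0.576) nor the H3K27me3 list (0.71, adjusted p = 0.1314) passed.

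Cumulus clones shared array set, not slide or scan day, with female IVF blastocysts. Here 839 genes differed (308 higher, 531 lower), and 219 with scan day as a block. Dpf1 fell by 5.19 (adjusted p = 8.264e-05) to -3.25 ± 0.17 (n = 3) from 1.94 ± 0.52 (n = 3), Ly75 by 5.03, Asz1, a germ cell protein of the piRNA pathway, by 3.68 and Mbnl3, an X-linked splicing factor, by 3.53. Snhg11, a noncoding RNA, rose by 2.96, Slc38a4 by 2.04 (adjusted p = 0.0005558) and Gab1 by 2.00 (adjusted p = 0.003714). These genes passed with any 1 array left out. Of 54 named genes that passed, 42 did not pass without some array, 36 of them without cumulus replicate 2. Without that array 224 genes passed, 458 without cumulus replicate 1, and 478 and 377 without IVF replicates 1 and 2.

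H3K27me3-dependent imprinted genes rose in cumulus clones, 2 of 14 (5 adjusted over the list alone; median 0.61, adjusted p = 0.0006862, and adjusted p = 0.0061 with an estimated correlation). Cholesterol synthesis rose by a median of 0.73, with 1 of 22 genes higher, also adjusted over the list alone (adjusted p = 1.093e-05, and adjusted p = 0.3618 with an estimated correlation). Ribosomal proteins fell, 6 of 81 (14 adjusted over the list alone; median -0.35, adjusted p = 3.455e-06), as did respiratory chain genes, 5 of 80 (7 adjusted over the list alone; median -0.42, adjusted p = 8.27e-05), both with adjusted p = 0.5675 with an estimated correlation. Primitive endoderm genes fell, 3 of 19 (4 adjusted over the list alone; median -0.93, adjusted p = 0.005811, and adjusted p = 0.5461 with an estimated correlation). That list did not pass without IVF replicate 3 (-0.64, adjusted p = 0.0814) or cumulus replicate 2 (-0.44, adjusted p = 0.142), nor in a fit of both groups alone (adjusted p = 0.0955) or with fry (adjusted p = 0.0935).

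**Figure D3:**
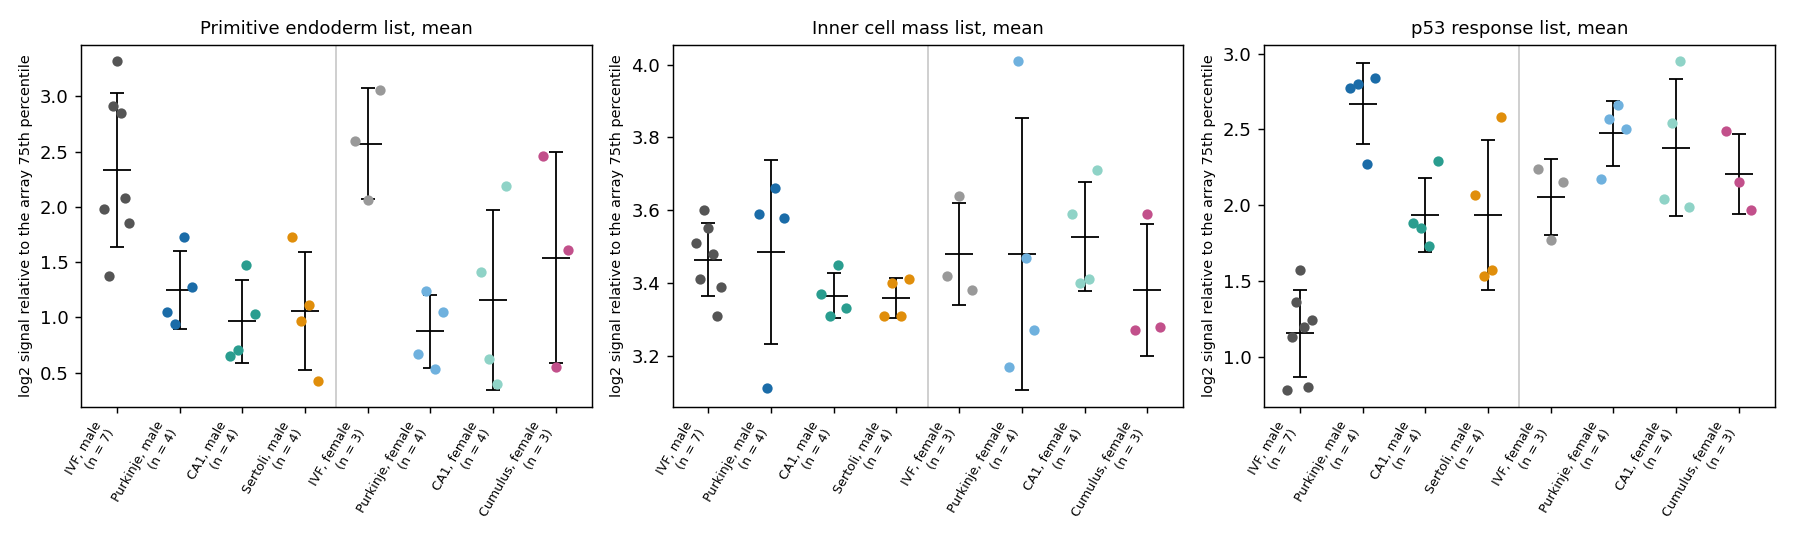
Mean log2 signal relative to the 75th percentile of the array (vertical axis) of the primitive endoderm, inner cell mass and p53 response lists, 1 point per blastocyst by group; bars are mean and SD. The primitive endoderm mean is 2.34 ± 0.70 (n = 7) and 2.57 ± 0.50 (n = 3) in male and female IVF blastocysts and 0.87 to 1.54 in the clone groups, and the p53 mean of male IVF blastocysts is 1.15 ± 0.29 (n = 7).

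Some genes moved one way in all 6 comparisons of clones with IVF blastocysts: 52 were higher and 75 lower. Of the lower ones 26 were X-linked, and of the higher ones none. Mgst2, a glutathione transferase, rose by 3.12 to 4.24 and Snhg11 by 2.47 to 3.32. Asz1 was at least 10.51-fold lower in each male clone group and fell by 4.02, 4.02 and 3.68 in the females. Foxa2, an endoderm transcription factor, changed by -4.35 to -3.26, Cibar1, a protein of the cilium, by -4.15 to -3.00, and Dusp9, an X-linked phosphatase of MAP kinases, by -3.71 to -2.56, and by -1.13 to -0.74 at another probe. In cumulus clones Mgst2, Foxa2 and Dusp9 each lost its call with some array left out, among them Foxa2 without cumulus replicate 2. Comparisons of the same sex share their IVF blastocysts, and the 3 female ones were too few to be divided between comparisons. Independent lists of these sizes would share 0.01638 and 0.002561 genes, which leaves out this sharing, and 20 simulations of unchanged groups gave at most 0, which leaves out all real effects. Neither shows how many genes the shared blastocysts alone would give.

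Cumulus clones and the male clones share no array, and their changes were compared across genes. The correlation was r = 0.389 with male Purkinje clones, 0.274 with male CA1 clones and 0.378 with Sertoli clones; genes are not independent replicates. Permuted labels reached 0.397, 0.362 and 0.34, and 1, 4 and 0 of 100 were as high. Genes lower in both numbered 187, 190 and 201, against 54.8, 70.7 and 57.3 from independent lists, and genes higher in both 146, 109 and 150, against 56.3, 54.5 and 46.3. In the authors' values the correlation with Purkinje and Sertoli clones was 0.209 and 0.183.

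**Figure D4:**
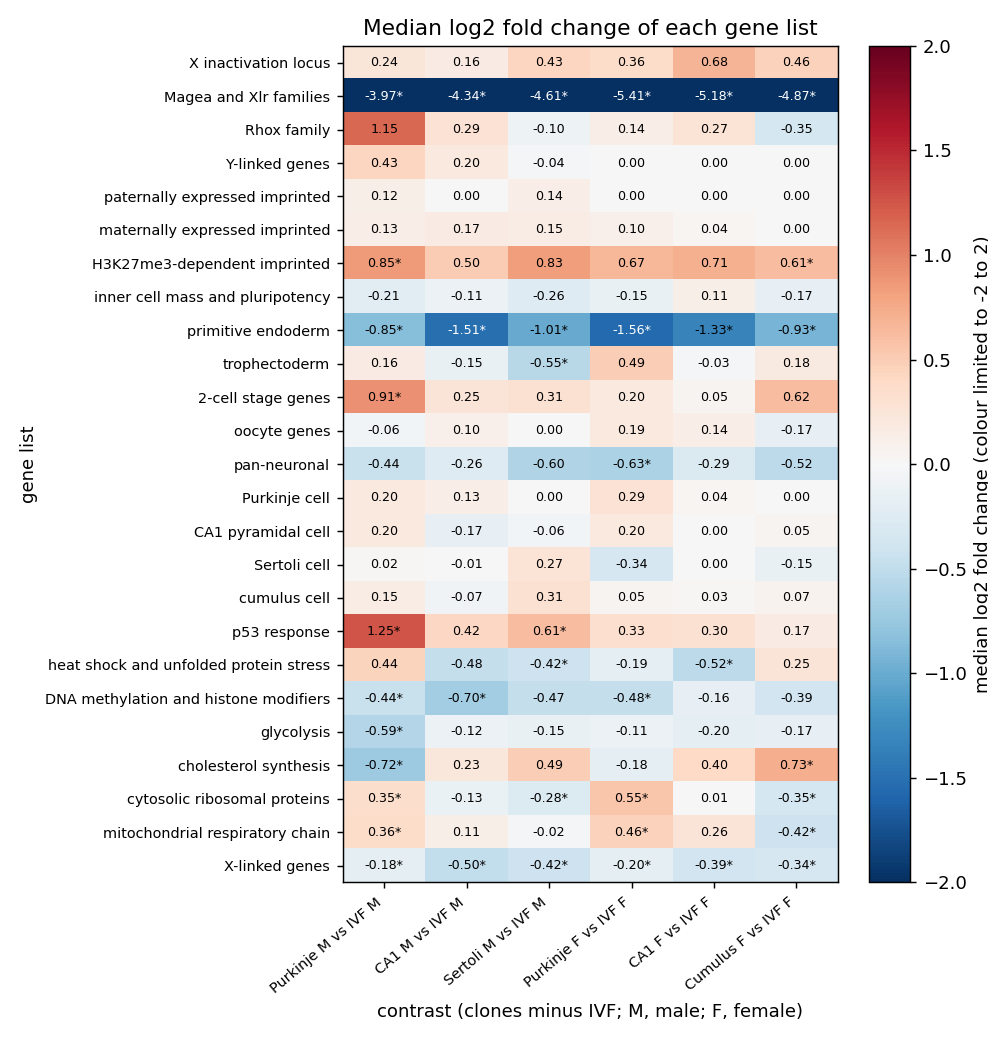
Median log2 fold change, clones minus IVF blastocysts, of each of 25 gene lists (vertical axis) in 6 comparisons (horizontal axis); red is higher, blue lower, colour is limited to 2 either way and an asterisk marks lists that passed. The Magea and Xlr families lie at -5.41 to -3.97 in all 6; ribosomal and respiratory chain medians of Purkinje clones turned negative after quantile normalization.

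Markers of the donor cells were measured to see whether clones kept expression of the donor. Purkinje cell markers had a median of 0.20 in male and 0.29 in female Purkinje clones, CA1 pyramidal markers -0.17 and 0.00 in male and female CA1 clones, Sertoli markers 0.27 in Sertoli clones and cumulus markers 0.07 in cumulus clones, and none of these lists passed in any of the 6 comparisons. Single members passed, such as Wfs1, a protein of the endoplasmic reticulum, up by 1.84 in male CA1 clones. Inner cell mass genes had medians between -0.26 and 0.11, paternally expressed imprinted genes between 0 and 0.14, maternally expressed ones between 0 and 0.17, oocyte genes between -0.17 and 0.19, Y-linked genes between -0.04 and 0.43, the Rhox family between -0.35 and 1.15 and the X inactivation locus between 0.16 and 0.68, and none of these passed either.

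Male clones of different donors were compared. Donors of a sex lay on separate slides and scan days, so donor cannot be told from these. Both sexes of a neuronal donor shared a scan day. Purkinje and CA1 clones differed in 2922 genes, 1724 higher and 1198 lower in Purkinje clones, and in 1743, 1724 and 1811 without Purkinje replicates 3 or 4 or CA1 replicate 4. Junb, an immediate early transcription factor, was 3.04 higher on the log2 scale in Purkinje clones (adjusted p = 1.905e-06), Fgl1, a fibrinogen-like protein, 3.07 and Hspa8, a chaperone, 1.07. Mvd fell by 3.12 (adjusted p = 1.664e-05), Tfr2, a transferrin receptor, by 3.78, Padi3, a peptidylarginine deiminase, by 3.62 and Slc22a18 by 2.61. Heat shock genes were higher in 7 of 19 (median 0.72, adjusted p = 0.005269) and p53 response genes in 4 of 22 (0.66, adjusted p = 0.005162), and cholesterol synthesis was lower in 9 of 22 (-0.92, adjusted p = 2.224e-06); the counts were 8, 5 and 10 when adjusted over the list alone. With an estimated correlation their adjusted p were 0.3469, 0.5322 and 0.3469. After normexp the heat shock (adjusted p = 0.676) and p53 (adjusted p = 0.889) lists did not pass and their tests turned, and after quantile normalization the heat shock list did not pass (adjusted p = 0.123). Ribosomal proteins (median 0.40, adjusted p = 0.0001296, and adjusted p = 0.532 with an estimated correlation) turned to -0.11 after quantile normalization and after normexp. X-linked genes were higher (0.19, adjusted p = 0.02042, and adjusted p = 0.5322 with an estimated correlation), and not without Purkinje replicate 2 (adjusted p = 0.116) or CA1 replicate 2 (adjusted p = 0.146). Without the Purkinje arrays of low signal 594 genes passed, and X-linked genes did not pass (adjusted p = 0.0717).

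Male Purkinje and Sertoli clones differed in 757 genes, 532 higher and 225 lower in Purkinje clones, and in 420 and 371 without Purkinje replicates 3 or 4. Parm1, a mucin-like protein, was 2.88 higher and Hspa8 1.41 (adjusted p = 6.063e-05; 0.43 at another probe), and Mvd fell by 2.13. Trophectoderm genes were higher in 6 of 23 (median 0.61, adjusted p = 0.0001741), heat shock genes in 6 of 19 (0.73, adjusted p = 1.418e-05) and cholesterol synthesis lower in 8 of 22 (-1.26, adjusted p = 1.029e-13), each with adjusted p = 0.03859 with an estimated correlation; adjusted over the list alone the counts were 9, 7 and 17. The p53 response (0.64, adjusted p = 0.0004275, and adjusted p = 0.296 with an estimated correlation) also passed. After normexp the trophectoderm (adjusted p = 0.677), heat shock and p53 (adjusted p = 0.953 for both) lists did not pass and their tests turned. Ribosomal (0.48, adjusted p = 1.958e-17) and respiratory chain (0.25, adjusted p = 0.0001838) medians, with adjusted p = 0.2737 and 0.4534 with an estimated correlation, turned to -0.01 and -0.23 after normexp. The 2-cell stage list (0.56, adjusted p = 0.02507, and adjusted p = 0.3085 with an estimated correlation) did not pass without Purkinje replicate 4 (0.37, adjusted p = 0.524) or Sertoli replicate 3 (adjusted p = 0.0658), nor did X-linked genes (0.21, adjusted p = 0.006, and adjusted p = 0.3756 with an estimated correlation) without Purkinje replicate 2 (adjusted p = 0.0862). Without the Purkinje arrays of low signal 185 genes passed, and the 2-cell stage (0.30, adjusted p = 0.423) and X-linked (0.07, adjusted p = 0.0804) lists did not.

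Male CA1 and Sertoli clones differed in 1869 genes, 871 higher and 998 lower in CA1 clones, and in 762 and 1123 without CA1 replicate 4 or Sertoli replicate 1. Trim45, a ubiquitin ligase, was 4.21 higher (adjusted p = 5.624e-08; 1.07 at another probe), Parm1 3.93 and Oas3, an antiviral enzyme, 3.64; Fgl1 fell by 3.41 and Junb by 2.70 (-0.53 at another probe). Modifiers of DNA and histones (median -0.42, 6 of 28 lower and 1 higher, 8 and 1 adjusted over the list alone) and ribosomal proteins (0.18, 4 of 81 higher and 2 lower, also adjusted over the list alone) had adjusted p = 0.03804, and adjusted p = 0.1864 and 0.9461 with an estimated correlation. Modifiers did not pass without CA1 replicates 1, 2 or 4 (adjusted p = 0.0557, 0.0957 and 0.0748) or Sertoli replicates 3 or 4 (0.106 and 0.0806), nor ribosomal proteins without CA1 replicates 1 or 2 (0.0557 and 0.169) or Sertoli replicates 2 or 3 (0.229 and 0.119).

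In females, Purkinje and CA1 clones differed in 1740 genes, 977 higher and 763 lower in Purkinje clones, and in 935, 890 and 1099 without Purkinje replicates 3 or 4 or CA1 replicate 4. Sulf1, a sulfatase of heparan sulfate, was 3.81 higher, Bcl6, a transcriptional repressor, 3.23 and Hspa8 1.26, while Atp8a1, a lipid flippase, fell by 3.67 (-0.59 at another probe) and Eno2, a neuronal enolase, by 2.56. Heat shock genes were higher in 5 of 19, also adjusted over the list alone (median 0.55, adjusted p = 0.01323, and adjusted p = 0.487 with an estimated correlation), and not after quantile normalization (adjusted p = 0.472) or normexp (adjusted p = 0.715). Cholesterol synthesis was lower in 3 of 22 and higher in 1 (8 and 1 adjusted over the list alone; -0.56, adjusted p = 0.01266, and adjusted p = 0.6475 with an estimated correlation), and not without Purkinje replicate 1 (adjusted p = 0.259), CA1 replicate 2 (adjusted p = 0.099) or CA1 replicate 4 (adjusted p = 0.0517). Ribosomal proteins were higher in 33 of 81 (41 adjusted over the list alone; 0.52, adjusted p = 1.418e-16, and adjusted p = 0.487 with an estimated correlation) and did not pass after quantile normalization (adjusted p = 0.382) or normexp (adjusted p = 0.641). Without the Purkinje arrays of low signal, with 1 left, the heat shock median was 0.34.

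Cumulus clones differed from female Purkinje clones in 2954 genes (2267 higher and 687 lower in Purkinje clones) and from female CA1 clones in 3049 (2191 higher and 858 lower in CA1 clones), comparisons that cross the array sets. Without cumulus replicate 2 the totals were 1868 and 1790, and without CA1 replicate 1 the CA1 total was 1796. Pdk2, a kinase of pyruvate dehydrogenase, was lower in both, by -5.92 and -5.94. F9, a clotting factor, was 3.68 higher in Purkinje clones (adjusted p = 9.017e-07) and Cidea 3.49, and H19, an imprinted noncoding RNA, fell by 4.14. Hand1 was 3.69 higher in CA1 clones. Ribosomal proteins and respiratory chain genes were higher in Purkinje clones (57 of 81, median 0.91, adjusted p = 3e-22; 49 of 80, 0.84, adjusted p = 1.399e-13; 64 and 60 adjusted over the list alone), with adjusted p = 0.3744 and 0.4022 with an estimated correlation, and did not pass after normexp (adjusted p = 0.815, and 0.671 with a turned test). Respiratory chain genes were also higher in CA1 clones (37 of 80 higher and 2 lower, 46 and 3 adjusted over the list alone; 0.70, adjusted p = 4.9e-07, and adjusted p = 0.8561 with an estimated correlation), and not after normexp (adjusted p = 0.106). Ribosomal proteins in CA1 clones (0.44, adjusted p = 0.03246, and adjusted p = 0.8561 with an estimated correlation) did not pass without CA1 replicate 1 (0.30, adjusted p = 0.369) or cumulus replicate 3 (0.37, adjusted p = 0.159) or after normexp, where the test turned (adjusted p = 0.856), nor modifiers of DNA and histones in Purkinje clones (-0.30, adjusted p = 0.02466, and adjusted p = 0.225 with an estimated correlation) without Purkinje replicate 1 (adjusted p = 0.0546) or cumulus replicate 1 (adjusted p = 0.051). Cholesterol synthesis was lower in Purkinje clones (-0.84, adjusted p = 4.508e-05, and adjusted p = 0.441 with an estimated correlation). Heat shock genes were lower in CA1 clones (-0.45, adjusted p = 0.0005789, and adjusted p = 0.3468 with an estimated correlation), and not without cumulus replicate 1 (adjusted p = 0.0571). Without the Purkinje arrays of low signal only 1 was left.

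Whether the change from IVF blastocysts differed between the sexes was tested by interactions. For Purkinje clones 9 genes passed, 7 with a higher change in males, and 1209 at an unadjusted p under 0.05. The total was 16 without male Purkinje replicate 2, 15 without female Purkinje replicate 1, 14 and 19 without male IVF replicates 3 and 5, and 20 without either of female IVF replicates 2 and 3. Without the Purkinje arrays of low signal, with 2 male and 1 female left, 7 of 26 had a higher change in males, and in the authors' values 4 of 11. Xist passed (adjusted p = 0.006226), with a size that the floor leaves open in males, and Btg2 differed by 2.24, where other probes gave -0.24 and -0.14. For CA1 clones 170 genes passed, 93 with a higher change in males, and 2155 at an unadjusted p under 0.05; the total was 96 without male CA1 replicate 4 and 108 without female IVF replicate 1. Rhox5 differed by 4.33 (adjusted p = 0.01234) and Ash1l, a histone methyltransferase, by -2.67. After normexp background correction limma called 0 genes in both.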

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

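No test of this part was chosen after its result had been seen. In 3 cases 1 male Purkinje clone lay far from the other 3 of its group. X-linked genes had a mean of -0.47 in replicate 1, against -0.11 to -0.04 in the others. The p53 response list had a mean of 2.27 in replicate 3, against 2.77 to 2.84. Inner cell mass genes had a mean of 3.11 in replicate 2, against 3.58 to 3.66. These were 3 of 66 tests of 11 measures, and chance gives about 1 in 20.

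The change of Purkinje clones from IVF blastocysts differed between males and females in 9 genes, and that of CA1 clones in 170. For these interactions 12 and 6 of 100 splits of the samples gave as many genes or more, so chance cannot be excluded. The highest other splits gave 1361 and 1596 genes, which points to a structure of the samples; the split with 1596 kept the CA1 clones of each sex, and so of each slide, together. Male minus female, 10 gene lists differed for Purkinje clones and none for CA1 clones. The median difference was 1.21 for the Magea and Xlr families (adjusted p = 0.0292), 1.55 for the Rhox family (adjusted p = 0.005479), 0.54 for Y-linked genes (adjusted p = 0.02063), 0.85 for primitive endoderm (adjusted p = 0.02497) and 0.8 for 2-cell stage genes (adjusted p = 0.0292). It was 0.49 for pan-neuronal genes (adjusted p = 0.04112), 0.86 for the p53 response (adjusted p = 3.357e-09), -0.69 for cholesterol synthesis (adjusted p = 1.38e-05), -0.25 for ribosomal proteins (adjusted p = 0.0001315) and -0.16 for the respiratory chain (adjusted p = 0.03894). With an estimated correlation between genes none of the 10 passed, and the lowest adjusted p was 0.1134, for p53. Y-linked genes lie near the floor in all females, so their difference holds little beyond the change in males.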

How the results depend on the processing

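The floor at 0.02 of the 75th percentile and the fit without the Purkinje arrays of low signal were chosen after the data had been seen. Of 865 calls of named genes, recomputed in 20237 values under all alternatives and left-out arrays, 16995 kept direction and call, 3211 lost the call and 31 turned direction. Of 72 gene list calls, 1470 of 1677 values stayed, 187 lost the call and 20 turned. Comparisons are written here as pairs with M for male and F for female. Lists called at the preset correlation rarely passed with an estimated one, from 11 to 1 in male Purkinje and 4 to 2 in male CA1 clones against IVF. With fry 16 list calls did not pass. They were primitive endoderm in Purkinje M/IVF M (adjusted p = 0.0702) and Cumulus F/IVF F (0.0935), the respiratory chain in Purkinje M/IVF M (0.053), Cumulus F/IVF F (0.0947) and Purkinje M/Sertoli M (0.0848), and ribosomal proteins in Sertoli M/IVF M (0.132), Cumulus F/IVF F (0.0947), Purkinje M/CA1 M (0.0512), CA1 M/Sertoli M (0.6), CA1 F/Cumulus F (0.257) and IVF M/IVF F (0.332). The others were cholesterol synthesis in Purkinje F/CA1 F (0.147), Purkinje F/Cumulus F (0.0736) and IVF M/IVF F (0.163), modifiers in Purkinje F/Cumulus F (0.0683) and X-linked genes in IVF M/IVF F (0.19). The share of higher genes depended on the scaling, and so did the median of all genes, not always the same way. For Purkinje F/IVF F the shift was -0.317 and 14.2% of calls were higher with scaling to the array median, 0.599 and 85.9% after normexp, and 0.417 and 80.2% in the authors' values, against 66.1%. For Purkinje M/IVF M the shifts were -0.128 (29.3% higher), 0.577 (80.6%) and 0.371 (75.8%), against 63.9%. Quantile normalization gave 46.3% and 47.2% higher for these pairs. The majority also turned with scaling to the median for CA1 M/IVF M (39.4% higher), Sertoli M/IVF M (41.9%), Purkinje M/CA1 M (40.1%), Purkinje M/Sertoli M (45.3%), Purkinje F/CA1 F (8.3%, shift -0.368), Purkinje F/Cumulus F (13.2%, shift -0.31) and the CA1 interaction (41.3%, shift -0.145). It turned with quantile normalization for Sertoli M/IVF M (46.3%), CA1 F/IVF F (43.3%), Purkinje M/CA1 M (46.5%) and CA1 M/Sertoli M (52.8%), and after normexp for Purkinje F/CA1 F (29.7%), CA1 M/Sertoli M (73.4%) and IVF M/IVF F (53.8%). For IVF M/IVF F it also turned with slide as a fixed block (93.2%) and within the slide of both sexes (98.6%), fits of 1 male array. For the Purkinje interaction it turned in the authors' values (36.4%) and without the arrays of low signal (26.9%), against 77.8%. Majorities near 50% also turned for CA1 M/Sertoli M with the floor at 0.02 (55.5%), at 2-fold (53.2%) and with the mean of all probes (50.8%), for Purkinje F/CA1 F at 2-fold (49.7%) and for the CA1 interaction with array weights (47%). Signal over background limits the Purkinje clones, with 75th percentiles of 229.7 to 838, and the Sertoli clones, with 45.2% to 46.1% of probes well above background; these limits were not ranked. No pair of groups had replicates of equal number that deviated together (r of -0.21 to 0.32). No count moved by over 1.5 times under a trended and robust prior, the replicate block, or filters on dim probes. Except where fewer samples or a size limit explain a lower count, the cause was not tested.

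After normexp the counts were 8610 for Purkinje M/IVF M, 2835 for CA1 M/IVF M, 1724 for Sertoli M/IVF M, 7228 for Purkinje F/IVF F, 466 for CA1 F/IVF F and 159 for Cumulus F/IVF F. They were 7654 for Purkinje M/CA1 M, 337 for Purkinje F/CA1 F, 4248 for Purkinje M/Sertoli M, 267 for CA1 M/Sertoli M, 6439 for Purkinje F/Cumulus F, 599 for CA1 F/Cumulus F and 13 for IVF M/IVF F. Limma called 0 for the Purkinje interaction and 0 for the CA1 interaction, against 1209 and 2155 at an unadjusted p under 0.05 before normexp. Ribosomal medians were -0.177 for Purkinje M/IVF M, 0.096 for Purkinje F/IVF F, -0.11 for Purkinje M/CA1 M, -0.013 for Purkinje M/Sertoli M and 0.251 for CA1 F/Cumulus F. Respiratory chain medians were -0.168 for Purkinje M/IVF M, 0.027 for Purkinje F/IVF F, -0.232 for Purkinje M/Sertoli M and 0.384 for Purkinje F/Cumulus F. The test against other genes also turned for p53 (0.265) and heat shock (0.238) in Purkinje M/CA1 M, and for trophectoderm (0.379), p53 (0.403) and heat shock (0.393) in Purkinje M/Sertoli M. The X-linked shift of Purkinje M/IVF M was -0.141. Genes that turned were Aldoa (-0.08) in Purkinje F/IVF F, Gata6 (-0.001) and Gng13 (0.036) in Purkinje M/CA1 M, and Eno1 (0.167) and Krt8 (-0.173) in Purkinje F/Cumulus F.

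Quantile normalization turned Dppa5a in Purkinje M/IVF M (-0.016), Purkinje F/IVF F (-0.148), Purkinje M/CA1 M (-0.106), Purkinje F/CA1 F (-0.148), Purkinje M/Sertoli M (-0.083) and Purkinje F/Cumulus F (-0.086). It also turned Hsph1 in Purkinje F/CA1 F (-0.232) and Hspa8 (-0.065) and Krt8 (-0.185) in Purkinje F/Cumulus F. Ribosomal medians became -0.096 in Purkinje M/IVF M and -0.112 in Purkinje M/CA1 M, respiratory chain medians -0.048 in Purkinje M/IVF M and -0.023 in Purkinje F/IVF F, and the Purkinje interaction counted 14. Scaling to the array median gave 509 for Cumulus F/IVF F, 1914 for Purkinje M/CA1 M, 3146 for Purkinje F/CA1 F, 408 for Purkinje M/Sertoli M, 1181 for CA1 M/Sertoli M, 145 for IVF M/IVF F and 18 for the Purkinje interaction. In Purkinje F/Cumulus F it turned Hspa8 (-0.041), Hspe1 (-0.043), Dppa5a (-0.006) and Krt8 (-0.182), all by less than the shift of all genes. The authors' values gave 4947 for Purkinje F/IVF F, 1210 for Purkinje M/Sertoli M and 5596 for Purkinje F/Cumulus F, and correlations of cumulus with Purkinje M and Sertoli clones of 0.209 and 0.183.

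A strict filter turned Cyp11a1 in Sertoli M/IVF M (-0.031). The mean of all probes turned Slc38a1 in CA1 M/IVF M (-0.019) and Purkinje F/Cumulus F (-0.036), Rps13 in Purkinje F/IVF F (-0.191), Ndufv3 in CA1 F/IVF F (-0.05), Rps24 in Cumulus F/IVF F (0.041), Gata6 in Purkinje M/CA1 M (-0.037), Rpl11 in Purkinje M/Sertoli M (-0.114), Sall4 in Purkinje F/Cumulus F (0.087), and Nap1l4 in CA1 F/Cumulus F (-0.399). Fits of the compared groups alone gave 1824 for Purkinje F/IVF F, 756 for CA1 F/IVF F, 229 for Cumulus F/IVF F, 626 for Purkinje F/CA1 F, 315 for Purkinje M/Sertoli M, 1862 for CA1 F/Cumulus F and 20 for IVF M/IVF F. Array weights gave 1291 for Cumulus F/IVF F, 4721 for Purkinje M/CA1 M, 3626 for Purkinje F/CA1 F, 2034 for Purkinje M/Sertoli M, 4664 for CA1 M/Sertoli M, and 18 and 330 for the Purkinje and CA1 interactions.

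With scan day as a random block the counts were 2591 for Sertoli M/IVF M, 1780 for Purkinje F/IVF F, 1004 for CA1 F/IVF F, 219 for Cumulus F/IVF F, 1381 for Purkinje M/CA1 M, 596 for Purkinje F/CA1 F and 249 for Purkinje M/Sertoli M. They were 577 for CA1 M/Sertoli M, 1677 for Purkinje F/Cumulus F, 1599 for CA1 F/Cumulus F and 26 for IVF M/IVF F. For IVF M/IVF F slide as a random block gave 40 (9 higher, 31 lower) and as a fixed block 44 (41 higher, 3 lower), where the ribosomal median was -0.184, as it was within the slide of both sexes. A minimum of 2-fold left 2474 for Purkinje M/IVF M, 2928 for CA1 M/IVF M, 2309 for Sertoli M/IVF M, 2063 for Purkinje F/IVF F, 1730 for Purkinje M/CA1 M, 1027 for Purkinje F/CA1 F, 459 for Purkinje M/Sertoli M, 1070 for CA1 M/Sertoli M, 1837 for Purkinje F/Cumulus F and 1995 for CA1 F/Cumulus F. With an estimated correlation the X-linked shifts of -0.261, -0.531, -0.44, -0.288, -0.475 and -0.323 for the 6 clone groups against IVF did not pass. The floor at 0.02 gave 1749 for Purkinje M/Sertoli M and 14 for the Purkinje interaction. Without the 5 Purkinje arrays of low signal, with 2 male and 1 female left, the counts were 1682 for Purkinje M/IVF M, 309 for Purkinje F/IVF F, 594 for Purkinje M/CA1 M, 83 for Purkinje F/CA1 F, 185 for Purkinje M/Sertoli M, 555 for Purkinje F/Cumulus F and 26 for the Purkinje interaction. Acat2 in Purkinje F/IVF F (-0.102) and Hspa8 in Purkinje F/Cumulus F (-0.026) turned, and a gene of the Magea family in Purkinje F/CA1 F was 0.

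With each array left out in turn the counts were 8 to 20 for the Purkinje interaction, 96 to 222 for the CA1 interaction, 1724 to 3412 for Purkinje M/CA1 M, 371 to 945 for Purkinje M/Sertoli M, 28 to 249 for IVF M/IVF F, 762 to 1818 for CA1 M/Sertoli M and 890 to 2381 for Purkinje F/CA1 F. They were 224 to 661 for Cumulus F/IVF F, 1868 to 3082 for Purkinje F/Cumulus F, 1790 to 3337 for CA1 F/Cumulus F and 1326 to 2127 for CA1 F/IVF F, and the X-linked shift of cumulus clones was -0.431 to -0.182.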

Other observations

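The tests of primitive endoderm genes against the array set and against the inner cell mass were chosen only after the result had been seen. The p53 difference between the sexes of Purkinje clones goes with the IVF level. The mean of the list was 1.15 ± 0.29 (SD, n = 7) in male and 2.05 ± 0.25 (n = 3) in female IVF blastocysts. In clones it was 2.67 ± 0.27 and 2.48 ± 0.21 (n = 4 each) for male and female Purkinje, 1.94 ± 0.24 and 2.38 ± 0.45 (n = 4 each) for male and female CA1, 1.94 ± 0.49 (n = 4) for Sertoli and 2.2 ± 0.26 (n = 3) for cumulus nuclei. On the slide that held both sexes of IVF blastocysts the median of the list was -0.787 in the male, which is 1 array and shows no difference of the sexes by itself.

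Rhox5 had means of 7.17, 7.10 and 7.02 in male Purkinje, CA1 and Sertoli clones and 7.33, 6.54 and 6.49 in female Purkinje, CA1 and cumulus clones. The means in male and female IVF blastocysts, 1.00 and 4.77, lay further apart than those of the clones.

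Neuronal and Sertoli clones differed from IVF blastocysts in many genes, in comparisons that cross the array sets. If the array set made the difference, clones of the present set would differ as much from cumulus clones of the earlier set. The median absolute log2 change against cumulus clones was 1 times that against IVF in female Purkinje clones (0.472 and 0.474) and 1.14 times in female CA1 clones (0.478 and 0.421), at r = 0.6 and 0.56, against 0.43 simulated with no change. Of the genes that differed from IVF, 1407 of 3113 and 979 of 2096 also differed from cumulus clones in the same direction. Donor and array set cannot be told apart in these comparisons, and both a difference between the array sets and a difference between neuronal and cumulus clones stay open.

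X-linked genes were lower in all 6 clone groups. Cumulus clones had an X-linked shift of -0.32 within the earlier set, but lay on another slide than the female IVF arrays. Without cumulus replicate 2 the shift was -0.18 and did not pass (adjusted p = 0.055), nor did it pass with an estimated correlation. The X chromosome had the lowest median of 20 chromosomes in 6 of 6 comparisons, so no autosome fell as far. In cumulus clones its median was -0.34, against -0.16 for the lowest autosome. The count restates the X-linked fall, and comparisons of the same sex share their IVF blastocysts. It therefore does not decide on a cause. Whether the array set or slide makes the shift stays open. Silencing of X chromosomes in clones is a hypothesis found and tested on the same data.

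Primitive endoderm genes were lower in all 6 clone groups. In cumulus clones, within the earlier set, their median was -0.93, and it did not pass with fry or without IVF replicate 3 or cumulus replicate 2, so a difference between the array sets stays open. A smaller inner cell mass would lower inner cell mass genes as well. In male CA1, female Purkinje and female CA1 clones the inner cell mass median lay above that of primitive endoderm by at least 1.4. The SD of inner cell mass members (0.50, 0.80 and 0.49) is no error of this gap, so it excludes nothing. In male Purkinje, Sertoli and cumulus clones the smallest gap was 0.64 (SD of 0.77). A smaller inner cell mass stays open in all 6.

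Other splits of the same samples gave fewer genes than the real one for 11 comparisons (real value, highest other). In males against IVF these were 4515 and 2344 for Purkinje, 4894 and 2620 for CA1 and 4077 and 2074 for Sertoli clones, each the only 1 of 100 splits. In females they were 3113 and 2640 for Purkinje and 2096 and 1079 for CA1 clones. Between donors they were 2922 and 243 (male Purkinje and CA1), 757 and 18 (Purkinje and Sertoli), 1869 and 67 (CA1 and Sertoli), 1740 and 963 (female Purkinje and CA1), 2954 and 1915 (Purkinje and cumulus) and 3049 and 2319 (CA1 and cumulus). Each of these 8 was the only 1 of 35 splits. The highest other splits of female Purkinje clones put replicate 1, the array of highest signal, with the other group. Each clone group lay on a slide of its own, so donor and slide cannot be told apart by splits. For cumulus clones against IVF the 10 splits are too few for a share under 0.05 (839 and 9). Between male and female IVF blastocysts 15 of 100 splits gave at least the 69 genes of the real one, so chance cannot be excluded. The highest, with 3330, set male replicates 1, 6 and 7 against the rest, which points to a structure of the samples, and 2 of these share a slide. With slide as a random block 40 genes passed, 9 higher and 31 lower. As a fixed block the fit rests on 1 male array.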
